A study of Mus musculus with 24 samples.

How the data were processed

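The data are bulk RNA sequencing of jejunal epithelial cells from 4 male C57BL/6 mice aged 10 weeks. Per the labels' protocols, cells were released with EDTA, stained for CD73 and CD26 and sorted by FACS into 6 villus zones per mouse, and polyadenylated RNA was made into mcSCRB-seq libraries, which read the 3-prime end of transcripts and tag each molecule with a unique molecular identifier (UMI). The 24 libraries form 6 groups of 4, and the same mouse number in the labels joins the 6 zones of a mouse. Protein measurements were not used here.

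The authors deposited 1 table of raw UMI counts per gene for the 24 libraries. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.15.0.4 and the build was GRCm38. The name of the table points to zUMIs, while the aligner, its annotation release and its filters are not given in the sources used here. The table held 17811 gene identifiers, of which 131 had no count. All values were whole numbers, and library totals ranged from 806541 to 2266261 with a median of 1502948.5. Gene symbols were those of the deposited table. Of the identifiers, 17741 matched GENCODE M21, which gave coordinates on GRCm38. The deposited index column is headed as a barcode and was read here as a pool label, which the header does not state. Read so, it put 7 libraries in 1 pool (6 of mouse 1 and V1 of mouse 2), the other 5 of mouse 2 in another, and mice 3 and 4 in 1 pool of 6 each.

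Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr by zone (minimum count 10, minimum total 15), which left 9328, and libraries were scaled by TMM. A quasi-likelihood model with a mean per zone over all 24 libraries (18 residual degrees of freedom, robust dispersions) gave each contrast: the slope of log2 expression per zone, V6 minus V1, each step between neighbouring zones, the quadratic curvature, and all differences together. The slope takes the 6 zones as equally spaced. Calls used a Benjamini-Hochberg adjusted p under 0.05 over genes, within each contrast. The 31 gene lists were tested on the slope with camera of limma 3.58.1 (preset correlation 0.01) where at least 5 members were tested, which held for 27, with an adjusted p under 0.05 over lists. Camera with an estimated correlation and fry stand beside it. Counts per list were also adjusted over the list alone. CPM values are TMM-scaled means of 4 mice. Slopes of library values were tested by two-sided permutation of zones within mice (100000 resamples). Python tools were numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

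The named genes were chosen by a rule set before the data were examined. For the trend and for tip against bottom it took the 10 largest rises and falls among called genes with a mean of at least 50 CPM, the same direction in all 4 mice and no provisional name. For each list it took up to 4 members with the smallest adjusted p and the most abundant one. For curvature it took the 5 smallest adjusted p in each direction with the extreme in V2 to V5, and for each step the 3 largest rises and falls. Genes named outside the rule are said to be so. Some genes that the rule selects are not reported here by name.

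Whether mouse numbers pair the libraries was checked on their counts. Deviations from the zone means correlated with a mean r of 0.608 between zones of the same mouse (lowest 0.311, above 0.1 in 60 of 60 pairs). Between different mice the mean r was -0.202, which adds little, since deviations from a zone mean cancel over its mice. All 24 libraries had their highest mean r with the other zones of their own mouse. The model with mouse as a block (15 residual degrees of freedom) is therefore given beside the model without it. No 2 libraries were copies: over 36 pairs of the same zone, counts differed by 3.77 to 32.7 times the sampling noise (chi-square per degree of freedom). The first principal component held 51.5% of the variance, and zone explained 79.8% of it. Mouse explained 76.4% of the second, which held 12.8%.

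The test was run on simulated counts. For the linear trend over 9074 genes, it recovered 60.2% of 98 genes with a slope of 0.2 and 98% of 100 genes with a slope of 0.4, with 7 false calls (4.27% of calls). For the step from V1 to V2 over 9080 genes, it recovered 44.8% of 96 genes changed by a log2 of 1 and 90.3% of 93 genes changed by 2, with 2 false calls. With no simulated change it called 0 genes in every contrast. The simulated libraries were drawn independently, without shared effects of a mouse or goblet cell differences between zones. These rates need not hold for the real libraries.

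The alternatives were mouse as a block, DESeq2 size factors, scaling by total UMIs, no filter, a mean of at least 50 CPM, removal of mitochondrially encoded genes, thinning to the smallest library with and without the block, DESeq2 1.42.0, limma-voom, leaving out each mouse or library, V2 to V6, V1 to V5, a model of the 2 zones of a comparison alone, and other list tests. Alternatives chosen after seeing the data were V3 to V6 with and without the block, V2 to V6 with the block, the library pool as a block, and mouse as a block with a goblet score (the mean log2 CPM of the goblet cell list) as a covariate.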

Results

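The data describe messenger RNA along the axis of the mouse jejunal villus, the finger-like fold that absorbs nutrients in the small intestine. Epithelial cells of 4 male C57BL/6 mice aged 10 weeks were stained for the surface proteins CD73 and CD26 and sorted into 6 zones. The zones run from V1, the most bottom one, through V2 (bottom), V3 (bottom-middle), V4 (middle) and V5 (middle-tip) to V6 (tip). Each mouse gave 1 bulk library per zone, so there were 4 libraries per zone and 24 in all. The libraries held between 806541 and 2266261 unique molecular identifiers (UMIs, molecules counted once each), with a median of 1502948.5. Levels are given as CPM, the UMI count scaled to a common library total after TMM scaling, as mean ± SD of 4 mice, and slopes as log2 change per zone ± SE over the 24 libraries.

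Nt5e, the gene of CD73, had 1.13 ± 0.782 CPM in V1 and 269 ± 134 CPM in V6 (SD, n = 4), with a slope of 1.56 ± 0.11 (adjusted p = 1.1e-09). Dpp4, the gene of CD26, had 147 ± 42.4 CPM in V1, 504 ± 27.9 in V4 and 437 ± 64.2 in V6 (SD, n = 4), with a slope of 0.27 ± 0.030 (adjusted p = 1.5e-07). Both were higher in V6 than in V1 in 4 of 4 mice. Over V3 to V6, with mouse in the model, the slope of Nt5e was 1.85 (adjusted p = 1.7e-15), while that of Dpp4 was -0.040 (adjusted p = 0.646). Nt5e (ENSMUSG00000032420) lies on chromosome 9 (88327197 to 88372092) and Dpp4 (ENSMUSG00000035000) on chromosome 2 (62330073 to 62412231) of GRCm38. Because the sort used both proteins, their transcripts are a check of the zone labels and no separate finding. They do not settle the order of V4 and V5. From V4 to V5 Nt5e rose in mice 1, 2 and 3, but in mouse 4 it had 27.2 CPM in V4 and 20.9 in V5. On the first principal component, V5 lay nearer V1 than V4 did in mice 2, 3 and 4, and farther from V1 in mouse 1.

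The linear trend asked which transcripts rose or fell from the bottom to the tip. Adenosine deaminase, Ada, rose from 89.6 ± 45.3 to 4782 ± 1223 CPM (SD, n = 4; slope 1.21 ± 0.071), and the purine nucleoside transporter gene Slc28a2 from 47.6 ± 33.3 to 898 ± 258 CPM (slope 0.88 ± 0.10). Apoa4, an apolipoprotein of chylomicrons, rose from 888 ± 524 to 14966 ± 3011 CPM (slope 0.79 ± 0.070). The hormone gene Nts (neurotensin) rose from 5.39 ± 4.53 to 1474 ± 188 CPM (slope 1.30 ± 0.16). At the other end, the goblet cell mucin gene Muc2 fell from 2419 ± 846 to 348 ± 92.1 CPM (slope -0.57 ± 0.077), and the hormone gene Gip from 1329 ± 164 to 131 ± 27.7 CPM (slope -0.79 ± 0.13).

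In the edgeR quasi-likelihood test, 4189 of 9328 genes changed with the zone at an adjusted p under 0.05, 2063 higher toward the tip and 2126 higher toward the bottom. Among genes with a mean of at least 50 CPM, the same direction in all 4 mice and no provisional name, the 10 largest rises were those of Nt5e, Nts, Ada, Slc28a2, Apoa4 and 5 others. These included Afp, the gene of a fetal serum protein, with 1.09 ± 1.41 CPM in V1 and 386 ± 181 in V6 (adjusted p = 4.7e-07). The others were Clca4a (slope 1.21 ± 0.10), Reg4, a lectin of the Reg family (1.15 ± 0.16), Pmp22 (1.12 ± 0.066) and Susd2 (0.92 ± 0.051). Clca4a has close gene copies, and reads shared with them were not told apart here. Nts is at 102481756 to 102490486 of chromosome 10, Ada at 163726584 to 163750239 of chromosome 2 and Apoa4 at 46240696 to 46243459 of chromosome 9. The adjusted p of these rises ran from 3.9e-12 for Susd2 to 1.7e-05 for Reg4. Of the 10 largest falls under the same rule, 7 were secretory genes of the goblet cell list (Fcgbp, Muc2, Tff3, Clca1, Zg16, Ccl6 and Spink4), and the others were Gip, the kallikrein Klk1 (-0.52 ± 0.047) and Ido1, an enzyme of tryptophan breakdown (-0.51 ± 0.12). Ido1 varied widely between mice, with 464 ± 376 CPM in V1. The adjusted p of these falls ran from 1.2e-08 for Klk1 to 0.00233 for Ido1.

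With mouse as a block, 2572 genes were higher toward the tip and 2590 toward the bottom, and 4188 of the 4189 calls were shared. Scaling by the total UMI count alone moved the split to 1217 toward the tip against 3720 toward the bottom, since it shifted the median V6 minus V1 of all genes from -0.00071 to -0.34 (log2). Over V3 to V6 the test called 222 genes toward the tip and 2 toward the bottom, or 587 and 75 with mouse as a block. Adding a goblet score (the mean log2 CPM of the goblet cell list) to the block, an alternative chosen after seeing the data, left 154 toward the tip and 31 toward the bottom in edgeR. Zone and mouse explain 94.2% of that score. Without mouse 1 the split was 1510 against 1293.

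**Figure D1:**
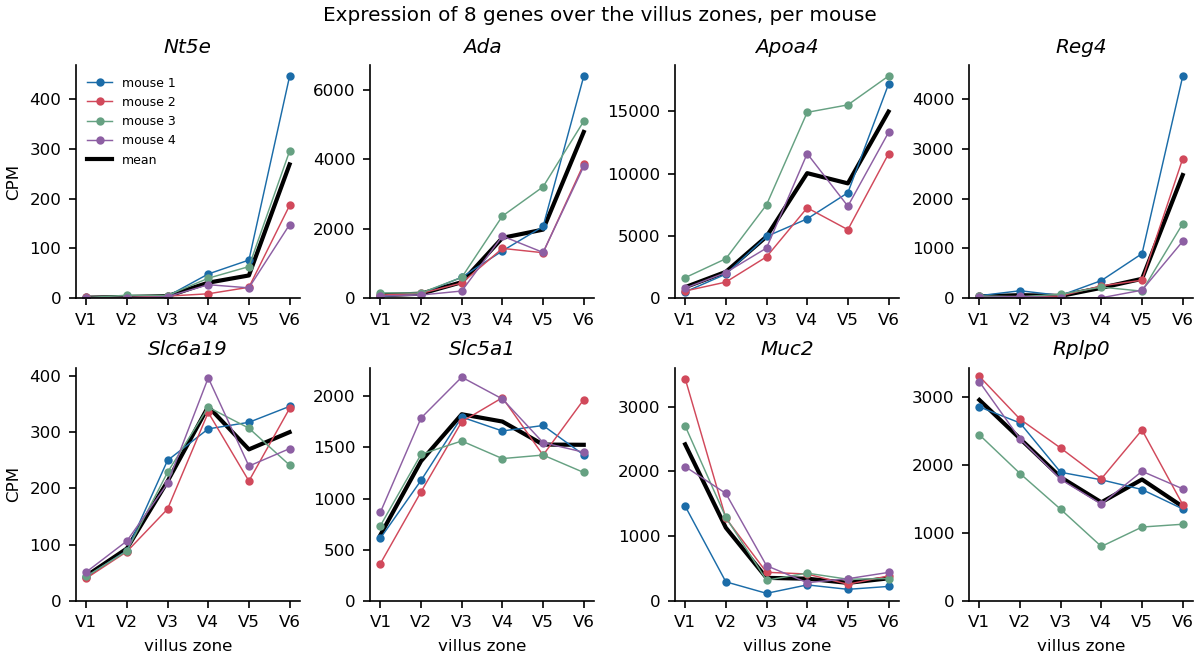
CPM of 8 genes (vertical axes, each from 0) in the 6 villus zones (horizontal axes); coloured points and lines are the 4 mice and the black line is their mean. Ada and Nt5e were highest in V6, Muc2 and the ribosomal protein gene Rplp0 in V1, and Slc5a1 had 1825 CPM in V3 and 1526 in V6.

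Most measured genes of nutrient absorption rose toward the tip. With an estimated correlation, the brush border, lipid absorption and microvillus lists were called (adjusted p = 0.0468 each), while amino acid transporters had an adjusted p = 0.0782 and sugar transport an adjusted p = 0.253. Sugar transport had a median slope of -0.034 over V2 to V6 and was called downward over V3 to V6 (median -0.095, camera adjusted p = 0.00208). Of the brush-border peptidases and disaccharidases, which digest peptides and sugars at the cell surface, 15 of 16 rose and 0 fell (adjusted over the list alone, 15 rose and 0 fell). Alkaline phosphatase, Alpi, went from 198 ± 33.3 to 974 ± 239 CPM (SD, n = 4; slope 0.44 ± 0.031), and trehalase, Treh, had a slope of 0.48 ± 0.042. Of the genes of lipid absorption and chylomicron assembly, 22 of 24 rose and 0 fell (adjusted over the list alone, 23 rose and 0 fell), among them Apoa1 (0.47 ± 0.059), the transcription factor gene Creb3l3 (0.48 ± 0.031), the fatty acid transporter gene Slc27a4 (0.41 ± 0.032) and the cholesterol transporter gene Npc1l1 (0.42 ± 0.045). Amino acid and peptide transporter genes rose in 9 of 14 cases and fell in 1, Slc1a1 (adjusted over the list alone, 9 rose and 2 fell). The neutral amino acid transporter gene Slc6a19 had a slope of 0.55 ± 0.028 and the peptide transporter gene Slc15a1 0.40 ± 0.048. Sugar transport and fructose metabolism rose in 9 of 14 genes and fell in 0 (adjusted over the list alone, 10 rose and 0 fell), with slopes of 0.19 ± 0.036 for the sodium-glucose cotransporter gene Slc5a1 and 0.23 ± 0.054 for the sugar transporter gene Slc5a9. Microvillus and cytoskeleton genes rose in 15 of 19 cases and fell in 2, the keratin genes Krt18 (-0.25 ± 0.037) and Krt19 (-0.20 ± 0.043) (adjusted over the list alone, 15 rose and 2 fell). Among those that rose were Plec (0.44 ± 0.035), Krt20 (0.38 ± 0.031) and Ezr (0.32 ± 0.027).

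In camera with a preset correlation of 0.01, the median slopes of these lists were 0.34 for the brush border (adjusted p = 4.0e-14), 0.29 for lipid absorption (2.2e-17), 0.17 for amino acid transporters (2.3e-06), 0.14 for sugar transport (0.00746) and 0.25 for the microvillus (3.3e-09). With mouse as a block, the microvillus list had an adjusted p = 0.0638 with an estimated correlation. Over V3 to V6, with mouse as a block, the median slopes were smaller or below 0, at 0.019 for the brush border, -0.033 for amino acid transporters, -0.091 for sugar transport, 0.066 for lipid absorption and 0.077 for the microvillus, and camera called sugar transport downward (adjusted p = 0.00253). There the calls of the brush border (adjusted p = 0.913) and of amino acid transporters (adjusted p = 0.386) ended. The sugar transport call also ended with genes of at least 50 CPM (adjusted p = 0.0891). The summed goblet cell transcripts fell over the same lower zones, from 75430.1 ± 25425 CPM in V1 to 12486 ± 5117 in V3 (SD, n = 4).

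**Figure D2:**
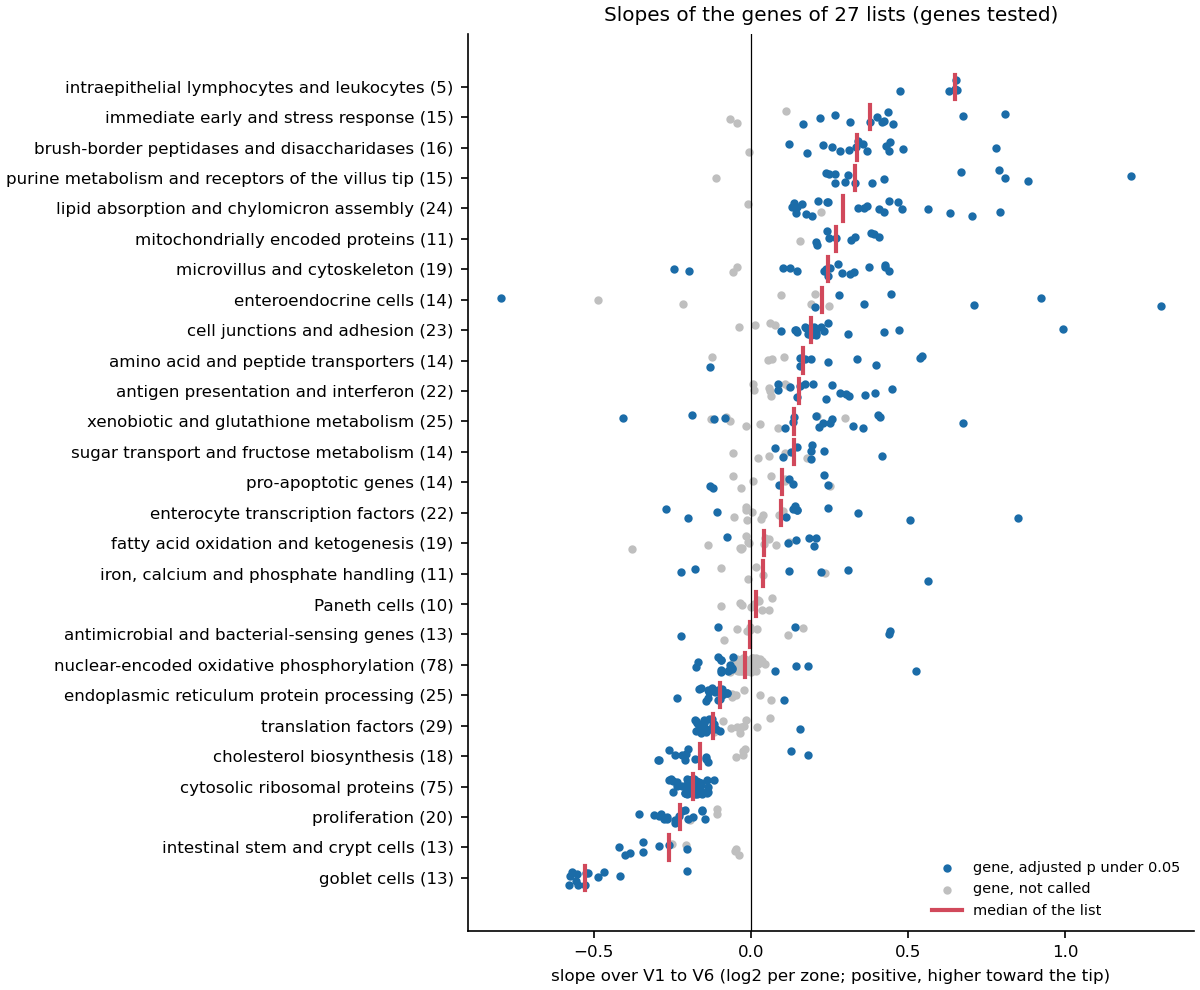
Slopes (log2 per zone, horizontal axis) of the genes of the 27 lists with 5 or more tested members (number tested after each name); each point is a gene, blue where its adjusted p was under 0.05, and the red bar is the median of the list. The medians ran from -0.53 for the goblet cell list to 0.65 for the lymphocyte and leukocyte list.

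Most measured genes of the tip, stress, junction and antigen presentation lists rose as well. With an estimated correlation the purine and tip list was called (adjusted p = 0.0468), while immediate early genes had an adjusted p = 0.0783, junctions an adjusted p = 0.0800, antigen presentation an adjusted p = 0.271 and xenobiotic metabolism an adjusted p = 0.368. Of the genes of purine metabolism and receptors known from the villus tip, 14 of 15 rose and 0 fell (adjusted over the list alone, 14 rose and 0 fell). Ada belongs to this list, as do the phosphodiesterase gene Enpp3 (0.79 ± 0.069) and Ifrd1 (0.67 ± 0.064). Immediate early and stress response genes rose in 12 of 15 cases and fell in 0 (adjusted over the list alone, 12 rose and 0 fell), among them Jun (0.68 ± 0.070), Fos (0.42 ± 0.052) and Zfp36 (0.40 ± 0.039). Fos and Junb are among the genes that stand in both lists. Cell junction and adhesion genes rose in 19 of 23 cases and fell in 0 (adjusted over the list alone, 21 rose and 0 fell). The laminin gene Lama3 went from 2.33 ± 0.911 to 63.8 ± 22.8 CPM (SD, n = 4; slope 0.99 ± 0.082), and Epcam and beta-catenin, Ctnnb1, had slopes of 0.23 ± 0.030 and 0.21 ± 0.028. Antigen presentation and interferon genes rose in 15 of 22 cases and fell in 0 (adjusted over the list alone, 16 rose and 0 fell), with B2m at 0.24 ± 0.042, H2-K1 at 0.30 ± 0.050 and Irf7 at 0.26 ± 0.038. Xenobiotic and glutathione metabolism was mixed, with 13 of 25 genes up, such as Cyp3a11 (0.68 ± 0.10) and Cyp2d26 (0.41 ± 0.049), and 4 down, such as Gsta4 (-0.41 ± 0.075) and Gpx1 (-0.19 ± 0.043) (adjusted over the list alone, 14 rose and 6 fell). Cyp3a, H2 and Gsta genes have close copies, and shared reads were not told apart here. Leukocyte transcripts rose beside the antigen presentation genes, from a summed 32.5 ± 25.7 CPM in V1 to 282 ± 21.9 in V6 (SD, n = 4).

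Median slopes were 0.33 for the purine and tip list (camera adjusted p = 8.9e-14), 0.38 for immediate early genes (1.8e-07), 0.19 for junctions (4.4e-08), 0.15 for antigen presentation (4.3e-05) and 0.14 for xenobiotic metabolism (0.0141). Over V3 to V6, with mouse as a block, the median slopes were 0.25 (purine and tip; camera adjusted p = 1.1e-24), 0.32 (immediate early; 1.1e-24) and 0.17 (junctions; 2.2e-17), while the calls of antigen presentation (-0.018, adjusted p = 0.819) and of xenobiotic metabolism (-0.013, adjusted p = 0.500) ended. The xenobiotic call also ended over V2 to V6 (median 0.076, adjusted p = 0.569) and with genes of at least 50 CPM (adjusted p = 0.151). These camera values used the preset correlation of 0.01. Over all zones the estimated correlation was 0.29 for the purine and tip list and 0.32 for immediate early genes. Values with an estimated correlation are not given for V3 to V6, so the small adjusted p there are no measure of certainty.

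Most measured genes of protein synthesis, of dividing and crypt cells, of cholesterol synthesis and of the endoplasmic reticulum fell toward the tip. None of their 6 lists was called with an estimated correlation, with an adjusted p = 0.170 for ribosomal proteins, an adjusted p = 0.150 for translation factors, an adjusted p = 0.349 for proliferation, an adjusted p = 0.253 for stem and crypt genes, and an adjusted p = 0.186 for both cholesterol biosynthesis and the endoplasmic reticulum. Of the genes of cytosolic ribosomal proteins, 74 of 75 fell and 0 rose (adjusted over the list alone, 0 rose and 75 fell), by similar amounts: Rplp0 went from 2963 ± 395 to 1389 ± 215 CPM (SD, n = 4; slope -0.20 ± 0.040), with a slope of -0.19 ± 0.026 for Rpl21. Rplp1 had -0.14 without passing the test, though with mouse as a block all 75 fell. Translation factor genes fell in 18 of 29 cases, such as Eef1a1 (-0.15 ± 0.035) and Eif3l (-0.17 ± 0.029), and rose in 1, Eif6 (0.16 ± 0.021), whose product acts in making the large ribosomal subunit (adjusted over the list alone, 2 rose and 18 fell). Of the proliferation genes, 17 of 20 fell, among them Birc5 (-0.23 ± 0.049) and Tubb5 (-0.21 ± 0.049), and 0 rose (adjusted over the list alone, 0 rose and 18 fell). Of the stem and crypt cell genes, 8 of 13 fell, such as Slc12a2 (-0.42 ± 0.091) and Ascl2 (-0.34 ± 0.090), and 0 rose (adjusted over the list alone, 0 rose and 10 fell). Ascl2 was low throughout, at 13.4 ± 3.40 CPM in V1. Cholesterol biosynthesis fell in 12 of 18 genes, such as Cyp51 (-0.30 ± 0.046) and Fdft1 (-0.29 ± 0.046), and rose in 2, among them Sc5d at 0.13 ± 0.024 (adjusted over the list alone, 2 rose and 12 fell). Genes of protein processing in the endoplasmic reticulum fell in 17 of 25 cases and rose in 1 (adjusted over the list alone, 1 rose and 17 fell), with Pdia6 at -0.23 ± 0.036 and Manf at -0.16 ± 0.029.

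Median slopes were -0.18 for ribosomal proteins (camera adjusted p = 1.3e-21), -0.12 for translation factors (1.2e-04), -0.22 for proliferation (1.6e-04), -0.26 for stem and crypt genes (0.00473), -0.16 for cholesterol biosynthesis (0.00361) and -0.097 for the endoplasmic reticulum (1.6e-04). The goblet cell transcripts moved in the same direction (75430.1 ± 25425 CPM in V1 and 12180.1 ± 2878 in V6; SD, n = 4). With mouse and a goblet score in the model the median slope of the ribosomal protein list was -0.15 with 0 of 75 genes called. Camera with the preset correlation still called that list downward there. In the same model the calls of cholesterol biosynthesis (median 0.000372, adjusted p = 0.924) and of the endoplasmic reticulum (-0.00309, adjusted p = 0.991) ended, and that of cholesterol biosynthesis also ended with genes of at least 50 CPM (adjusted p = 0.521). Over V3 to V6, with mouse as a block, the medians were -0.056 (ribosomal proteins), -0.18 (proliferation) and -0.25 (stem and crypt). There the calls of translation factors (-0.046, adjusted p = 0.113), cholesterol biosynthesis (-0.00568, adjusted p = 0.798) and the endoplasmic reticulum (-0.040, adjusted p = 0.0606) ended.

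Mitochondrially encoded transcripts were lowest at the bottom. Of their protein genes, 10 of 11 rose and 0 fell (adjusted over the list alone, 10 rose and 0 fell), with slopes of 0.41 ± 0.038 for mt-Co1, 0.32 ± 0.031 for mt-Nd5 and 0.21 ± 0.040 for mt-Cytb, the most abundant. All mitochondrially encoded transcripts together took 3.31% ± 0.886 of the UMIs in V1, 9.45% ± 2.87 in V4 and 8.10% ± 1.21 in V6 (SD, n = 4). The slope of this share was 0.823 percentage points per zone (two-sided permutation test within mice, p = 0.00338). It was 0.317 over V2 to V6 (permutation p = 0.312), and -0.197 over V3 to V6 (permutation p = 0.646). Reads from nuclear genome copies of mitochondrial sequence were not told apart here. From V1 to V3, where this share went to 8.04% ± 2.21, goblet cell transcripts went from 75430.1 ± 25425 to 12486 ± 5117 CPM, and in V4 they were at 12535 ± 1409 CPM (SD, n = 4). Of the nuclear-encoded genes of oxidative phosphorylation, 4 of 78 rose, with Cox6b2 at 0.52 ± 0.045, 13 fell, with Atp5g2 at -0.17 ± 0.032, and 61 were not called (adjusted over the list alone, 4 rose and 11 fell). Adding mouse as a block, 4 rose and 23 fell. Fatty acid oxidation and ketogenesis genes rose in 5 of 19 cases and fell in 1 (adjusted over the list alone, 5 rose and 1 fell). Under the block for mouse, 9 rose and 3 fell. The peroxisomal genes Cat (0.19 ± 0.029) and Acaa1b (0.20 ± 0.032) were among those that rose.

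The median slope was 0.27 for the mitochondrially encoded list (camera adjusted p = 4.9e-06), which was called with an estimated correlation (adjusted p = 0.0468) but had an adjusted p = 0.114 with mouse as a block and an estimated correlation. Its call ended over V3 to V6 with mouse as a block (median 0.076, camera adjusted p = 0.149). The medians were -0.019 for nuclear-encoded oxidative phosphorylation (camera adjusted p = 0.177) and 0.041 for fatty acid oxidation (0.189), neither called by camera over all libraries. The fry test, which does not set a list against other genes, called fatty acid oxidation upward (adjusted p = 0.00585) but not oxidative phosphorylation (0.237). Camera called oxidative phosphorylation downward with scaling by total UMIs (median -0.086, adjusted p = 0.00321), with genes of at least 50 CPM (0.00579), without mouse 2 (0.0153), over V2 to V6 (0.0147) and over V3 to V6 (0.00816). Camera called fatty acid oxidation upward with no filter (0.0224).

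The remaining enterocyte lists were not called by camera over all libraries and held genes that moved both ways. Of the antimicrobial and bacterial-sensing genes, 3 of 13 rose, among them the immunoglobulin receptor gene Pigr (0.14 ± 0.029), and 2 fell, among them Lypd8 (-0.22 ± 0.051) (adjusted over the list alone, 3 rose and 2 fell). The model with mouse as a block had 5 that rose and 2 that fell. The abundant lectin gene Reg3b had 21396 ± 8086 CPM in V1 and 23538 ± 5365 in V6 (SD, n = 4) and did not pass the test (adjusted p = 0.850). Of the pro-apoptotic genes, 5 of 14 rose, with Casp8 at 0.23 ± 0.038, and 2 fell, with Bax at -0.12 ± 0.029 (adjusted over the list alone, 5 rose and 2 fell). Iron, calcium and phosphate handling had 4 of 11 genes up, with the phosphate transporter gene Slc34a2 at 0.56 ± 0.12, and 2 down, with the iron exporter gene Slc40a1 at -0.22 ± 0.084 (adjusted over the list alone, 5 rose and 2 fell). Enterocyte transcription factor genes rose in 9 of 22 cases, with Prdm1 at 0.85 ± 0.12, and fell in 3, with Ehf at -0.27 ± 0.062 and Cdx1 at -0.20 ± 0.047 (adjusted over the list alone, 11 rose and 3 fell). The camera adjusted p was 0.808 for the antimicrobial list, 0.240 for the pro-apoptotic list, 0.430 for mineral handling and 0.0599 for transcription factors. The fry test called the transcription factor list (adjusted p = 1.2e-05) and the pro-apoptotic list (0.00227) upward. It called neither the antimicrobial list (0.528) nor mineral handling (0.171). Camera called the transcription factor list upward with no filter (adjusted p = 0.00934), without mouse 2 (0.0292), without mouse 4 (0.0416), over V1 to V5 (0.0165) and with mouse and goblet score (0.0172). Camera called mineral handling upward with the library pool as a block (0.0467) and with mouse and goblet score (0.0122). In the antimicrobial list the median slope (-0.003) and the mean (0.066) differed in sign. Slc40a1, Ehf and Cdx1, like Slc1a1, Krt18, Krt19, Gsta4, Gpx1 and Rplp1, were named after their values were seen.

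Markers of other cell types moved along the axis too. All 13 tested goblet cell genes fell (adjusted over the list alone, 0 rose and 13 fell; median slope -0.53, camera adjusted p = 1.5e-16), from a summed 75430.1 ± 25425 CPM in V1 to 38249 ± 14465 in V2, 12486 ± 5117 in V3 and 12180.1 ± 2878 in V6 (SD, n = 4). The list was called with an estimated correlation (adjusted p = 0.0468), and had an adjusted p = 0.0609 with mouse as a block and an estimated correlation. This call ended over V3 to V6 with mouse as a block (median -0.026, camera adjusted p = 0.282). In V2 the library of mouse 1 held 16837 CPM of goblet transcripts, below the other 3 mice (42365, 45729 and 48063). Enteroendocrine genes rose in 7 of 14 cases and fell in 1, Gip (adjusted over the list alone, 7 rose and 1 fell; median slope 0.23, camera adjusted p = 0.0127). That call ended with an estimated correlation (adjusted p = 0.333). It also ended with genes of at least 50 CPM (adjusted p = 0.140). Over V1 to V5 the median slope of this list was -0.32 (camera adjusted p = 0.174), and its summed level was 2433 ± 377 CPM in V1, 679 ± 306 in V4, 911 ± 161 in V5 and 6560.0 ± 1693 in V6 (SD, n = 4). The 5 tested genes of intraepithelial lymphocytes and leukocytes all rose (adjusted over the list alone, 5 rose and 0 fell; median slope 0.65, camera adjusted p = 0.00248), with Ccl5 from 13.2 ± 13.1 to 128 ± 10.7 CPM and the granzyme gene Gzmb from 0.756 ± 0.783 to 9.94 ± 4.68 CPM (SD, n = 4). With an estimated correlation this list had an adjusted p = 0.186. None of the 10 Paneth cell genes was called (adjusted over the list alone, 0 rose and 0 fell; camera adjusted p = 0.904), though their summed level ranged from 2359.6 CPM in mouse 4 V4 to 44677 CPM in mouse 2 V5. The Paneth list had a median slope of 0.016, while camera placed it downward, and reads shared between its defensin genes were not told apart here. Of 4 tuft cell genes, 1 rose, Trpm5 (0.65 ± 0.13), and 0 fell (adjusted over the list alone, 1 rose and 0 fell). The single tested gene of B and plasma cells, Igha, was not called (adjusted p = 0.315), and no gene of the stromal and endothelial list or of the erythrocyte list was abundant enough to test. Stromal and endothelial genes summed to 6.46 ± 0.691 CPM in V1 and 12.7 ± 2.64 in V6, and erythrocyte genes to 13.1 ± 24.6 and 7.43 ± 12.2 CPM (SD, n = 4).

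**Figure D3:**
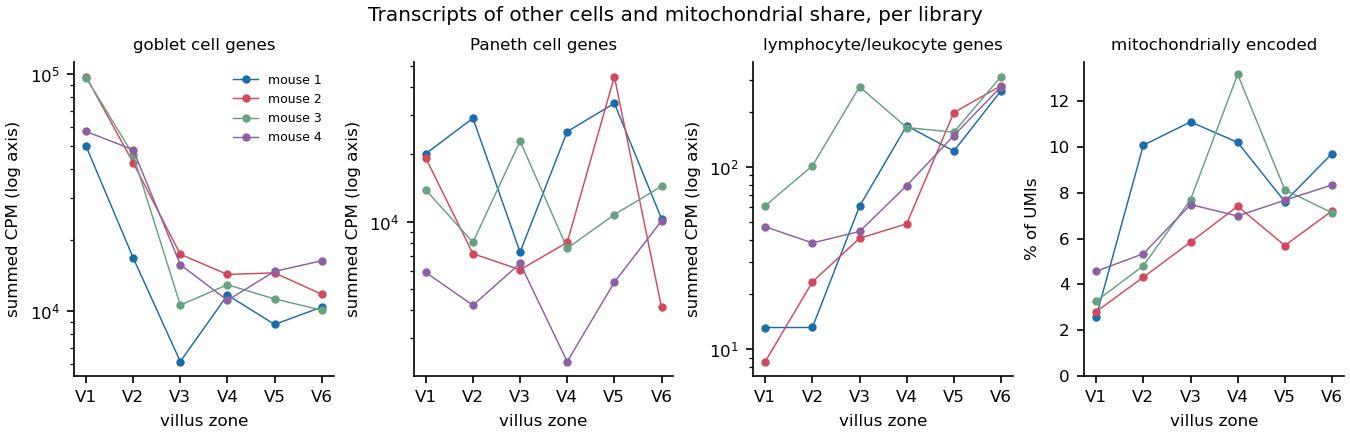
Summed CPM of the goblet cell, Paneth cell and lymphocyte and leukocyte lists (log axes) and percent of UMIs from mitochondrially encoded genes (axis from 0) in the 6 zones; each coloured line is a mouse. Goblet transcripts fell from a mean of 75430.1 CPM in V1 to 12486 in V3, and Paneth transcripts varied between libraries without a call along the axis.

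Across all lists, camera with the preset correlation called 20 of 27. The fry test, which asks whether the genes of a list move on balance 1 way and does not set them against other genes, called 23, and camera with an estimated correlation called 6. The number of 20 was not specific to the order of the zones: 12 of 100 orders of the zones within the mice, the true one included, gave 20 lists or more, and the highest of the others gave 21. The adjusted p of single lists was not checked against such orders. The preset correlation of 0.01 takes members as nearly independent, while the estimated one was 0.61 for ribosomal proteins and 0.67 for proliferation. Adjusted p values from the preset correlation can therefore be too small. The counts of single genes in each list do not rest on camera, but genes that move together are not separate findings. Of all 9328 tested genes, 2063 rose and 2126 fell. Rises of 3 of 13 antimicrobial and 5 of 19 fatty acid oxidation genes were near that share. The fall of 13 of 78 nuclear-encoded oxidative phosphorylation genes was below it.

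The tip was then set against the bottom directly. Nts was higher in V6 than in V1 by 8.11 ± 1.02 (log2 ± SE), Ada by 5.74 ± 0.42, Reg4 by 6.05 ± 0.99, Pmp22 by 5.29 ± 0.39 and Apoa4 by 4.07 ± 0.42, each in 4 of 4 mice. Gip changed by -3.35 ± 0.77, Tff3 by -2.83 ± 0.36, Muc2 by -2.80 ± 0.46 and Fcgbp by -2.76 ± 0.44, each lower in 4 of 4 mice. Gip lies on chromosome 11 (96024545 to 96030831) and Muc2 on chromosome 7 (141690340 to 141754693). The edgeR test called 3619 genes, 1882 higher at the tip and 1737 higher at the bottom, of which 1099 and 880 differed by 2-fold or more. Under scaling by the total UMI count the split was 1152 against 3102. With mouse and goblet score in the model it was 152 against 28. Without mouse 1, 982 genes were higher at the bottom.

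Any difference between zones was tested with all 5 contrasts together, which also finds profiles that turn. It called 2556 genes, or 4533 with mouse as a block. Of the 2556, 1095 (42.8%) had their highest zone mean in V1, like Rplp0 and Muc2, and 809 (31.7%) in V6, like Ada and Lama3. Another 476 (18.6%) had their highest mean in V4, like Slc6a19 and Aspa, while V2, V3 and V5 held the peaks of 27, 94 and 55 genes. The zone of the highest mean was not itself tested. From V4 to V5, 0 genes were called with or without mouse as a block. Curvature toward a high middle within V3 to V6 called 0, or 2 with the block. A highest mean in V4 can therefore be part of a plateau. Without mouse 1 the count was 1365 and without mouse 4 it was 1460.

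Curvature was tested over all 6 zones, where a steep change at the bottom also counts as a bend. Aspa, which encodes aspartoacylase, had 42.0 ± 8.71 CPM in V1, 195 ± 36.9 in V4 and 122 ± 17.1 in V6 (SD, n = 4; adjusted p = 1.1e-06). Slc6a19 and Slc7a15, both amino acid transporter genes, and the alanine aminotransferase gene Gpt also had their highest mean in V4, and Fam213a in V3 (adjusted p from 1.1e-06 for Slc6a19 to 3.4e-05 for Gpt). In V6 Slc6a19 still had 299.8 ± 52.2 CPM against 345 ± 37.8 in V4. Genes lowest in the middle included the hormone gene Sct (secretin), with 402 ± 145 CPM in V1, 158 ± 75.8 in V4 and 1659 ± 319.7 in V6, and the myosin gene Myl7, with 79.6 ± 6.58, 17.1 ± 1.56 and 91.4 ± 28.0 CPM (SD, n = 4; adjusted p = 4.0e-09). S100a6, Krt7 and Hepacam2 were highest in V1 and lowest in V3 or V4 (adjusted p = 3.4e-05 for Krt7). The goblet cell transcripts also fell over these zones, from 75430.1 ± 25425 CPM in V1 to 12486 ± 5117 in V3 (SD, n = 4). In the model with mouse and goblet score the call of Hepacam2 stayed, and those of S100a6 and Krt7 ended. The edgeR test called 426 genes curved toward a high middle, of which 362 had their peak in V2 to V5, and 267 toward a low middle, of which 252 had their lowest mean there. The counts were 1148 and 891 with mouse as a block, and 61 and 6 with the goblet score added. Within V3 to V6 edgeR called 0 and 2 (63 and 94 at an unadjusted p under 0.05), or 2 and 7 with mouse as a block. Leaving out mouse 4 left 138 and 123.

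The steps compared neighbouring zones. The zones are groups sorted on CD73 and CD26 and not measured distances, so a step does not place a change on the villus. From V1 to V2, Slc7a15 rose from 9.22 ± 0.587 to 29.5 ± 7.48 CPM (SD, n = 4; log2 change 1.68 ± 0.25), Bst1 by 1.73 ± 0.38 and the transcription factor gene Maf by 1.76 ± 0.44, while the thymosin gene Tmsb4x changed by -0.66 ± 0.16. From V2 to V3, Pmp22 rose by 1.94 ± 0.34, Susd2 by 1.84 ± 0.29 and Ada by 1.82 ± 0.36, and the goblet list genes Tff3 and Ccl6 changed by -1.68 ± 0.34 and -1.55 ± 0.31, with Klk1 at -1.53 ± 0.27. From V3 to V4, Ada rose again, by 1.91 ± 0.35, with Pmp22 (1.83 ± 0.33) and Pmepa1 (1.45 ± 0.22). From V5 to V6, Nts rose from 38.9 ± 33.2 to 1474 ± 188 CPM (log2 change 5.20 ± 0.85), Sct from a mean of 222 to 1659 ± 319.7 CPM and Chgb, a granin of endocrine cells, from 128 ± 72.6 to 817 ± 409 CPM (SD, n = 4).

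The edgeR test called 141 genes from V1 to V2 (133 up, 8 down), 27 from V2 to V3 (16 up, 11 down), 6 from V3 to V4 (all up) and 25 from V5 to V6 (all up). From V4 to V5 it called 0, with 171 genes at an unadjusted p under 0.05; DESeq2 and limma-voom called 0 as well. For the other 4 steps in order, DESeq2 called 309, 102, 55 and 41, and limma-voom 156, 18, 5 and 31. The edgeR model of the 2 zones alone called 0, 0, 2 and 10, with 1181, 703, 511 and 366 genes at an unadjusted p under 0.05, which ends every call of V1 to V2 and V2 to V3. The 5 counts were 1392 (858 up, 534 down), 447 (280 up, 167 down), 198 (180 up, 18 down), 0 and 140 (137 up, 3 down) in order with mouse as a block, and all of the calls without the block were kept with the same sign. Of the 25 genes that rose into the tip zone, 7 were among the 14 tested enteroendocrine list genes (among them Sct, Tph1, Nts, Chga and Chgb). Those outside the list included Nt5e, the gene of a sorted protein, and Scg2, Pcsk1, Resp18, Cartpt, Serpina1e and Gpx3. All of these but Nt5e were named after their values were seen. The list is short, so genes outside it may also come from endocrine cells, which was not tested. Without the block the step counts ranged from 0 to 107 (V1 to V2), 0 to 18 (V2 to V3), 0 to 2 (V3 to V4) and 13 to 26 (V5 to V6) with a mouse left out in turn.

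**Figure D4:**
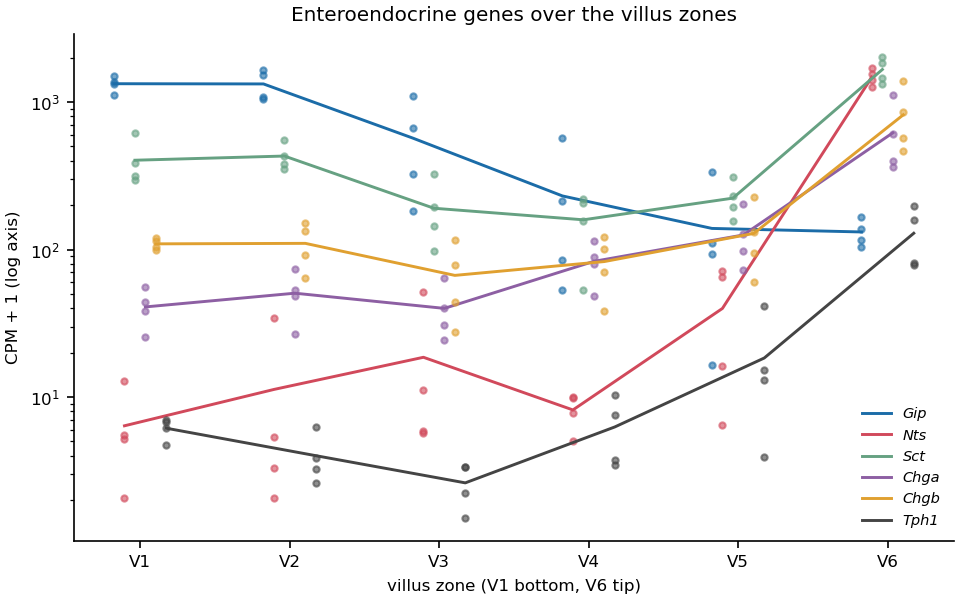
CPM plus 1 (log axis) of 6 enteroendocrine genes in the 6 zones; points are the 4 mice and lines join their means. Gip fell from 1329 CPM in V1 to 131 in V6, while Nts rose from 38.9 CPM in V5 to 1474 in V6.

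Total UMIs changed by -1585 per zone (two-sided permutation test within mice, p = 0.961). Genes detected per library changed by -82.5 per zone (permutation p = 0.147). After thinning every library to the smallest total the slope was -91.8 (permutation p = 0.00261).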

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

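The tests of V3 to V6 for ribosomal protein genes and of the endocrine genes, the comparison with a jackknife error, and the rule on how far zone and mouse explain the goblet score, were chosen only after the results were seen. Before these were added, the ribosomal protein list, the mitochondrially encoded list and the bottom-higher genes had each met the bound set beforehand against goblet cell RNA as the whole cause. Those bounds took no account of a score that follows the zone, so all of them are left open.

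In 9 of 114 groups of 4 mice, 1 library stood far from the other 3, by a gap of most of the range of the group. Chance gives about 1 in 20 such groups, or 5.7 of 114. Summed Paneth cell transcripts were high in mouse 1 V2 (29061 CPM against 4219 to 8076 in the other mice) and in mouse 3 V3 (22963 CPM against 6086 to 7298). Lymphocyte and leukocyte transcripts were high in mouse 3 V3 (275 CPM against 40.6 to 60.8). Erythrocyte transcripts were high in mouse 1 V1 (50.1 CPM against 0 to 1.86), mouse 2 V5 (86.0 CPM against 1.03 to 4.72) and mouse 1 V6 (25.5 CPM against 0 to 3.54). Clca4a was high in mouse 3 V1 (41.4 CPM against 10.9 to 16.1), Pmp22 in mouse 1 V6 (1447 CPM against 615 to 681) and Zg16 in mouse 4 V6 (7906 CPM against 4462 to 4893). Mouse 1 held 4 of the 9, mouse 3 held 3, and mice 2 and 4 held 1 each.

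Ribosomal protein genes and other genes were higher toward the bottom, as goblet cell transcripts were, so RNA of goblet cells in V1 and V2 could account for their higher level there. The 2113 bottom-higher genes outside the goblet list had a median slope of -0.18 with mouse as a block and -0.14 with the goblet score added, or 79.3% of it (jackknife error 21.8, 58.7% to 92.3% with a mouse left out), and 27 stayed called, as the median SE rose from 0.036 to 0.13. For the ribosomal protein list the same medians were -0.18 and -0.15 (jackknife error 0.059, -0.10 to -0.19 with a mouse left out), and 0 of 75 genes stayed called in edgeR. The list as a whole stayed called downward by camera with the preset correlation and the goblet score added. Over V3 to V6, where the goblet list had -0.026, the median of the ribosomal protein list was -0.056 (jackknife error 0.047). Zone and mouse explain 94.2% of the goblet score, so for both sets goblet cell RNA and the position on the villus cannot be told apart.

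From V1 to V3, mitochondrially encoded transcripts were higher where goblet cell transcripts were lower, so a dilution by goblet cell RNA in V1 and V2 could account for their rise. The goblet score, added to mouse as a block, moved their median slope from 0.27 to 0.17 (jackknife error 0.039, 0.13 to 0.19 with a mouse left out), and 0 of 11 genes stayed called in edgeR, as the median SE rose from 0.036 to 0.12. Their list as a whole stayed called upward by camera with the preset correlation in that model. The cause cannot be told apart, since the score follows the zone. Damage to cells during isolation and reads of nuclear copies were not tested, and the position on the villus stays open.

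Enteroendocrine genes moved apart along the axis, which was first seen in the data and is a hypothesis only. More endocrine cells of 1 fixed makeup toward the tip would raise all their hormone genes, yet Gip had a slope of -0.79 ± 0.13 while Nts had 1.30 ± 0.16. A different makeup of endocrine cells in each zone, or different content of the same cells, may account for this, and neither was tested. The sort by CD73 and CD26 could also take endocrine cells differently in each zone, which was not tested.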

How the results depend on the processing

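The alternatives over V3 to V6, V2 to V6 with mouse as a block, the library pool and the goblet score were chosen only after the results were seen, and the others before the data were examined. For values that moved or reversed, the cause was not tested unless it is given. The counts as reported were 2063 (trend toward the tip), 2126 (trend toward the bottom), 2556 (any difference), 1882 (higher in V6 than V1), 1737 (higher in V1 than V6), 426 (high middle), 267 (low middle), 20 (lists), 141 (V1 to V2), 27 (V2 to V3), 6 (V3 to V4), 0 (V4 to V5), 25 (V5 to V6). Calls without the block kept their sign with mouse as a block, other than 1 gene of the trend that was no longer called. Depth limits the genes of low count most: with libraries thinned to the smallest total, 7747 genes were tested, against 9328.

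Mouse as a block gave 4533 (any difference), 1148 (high middle), 891 (low middle), 1392 (V1 to V2), 447 (V2 to V3), 198 (V3 to V4), 140 (V5 to V6). Scaling by total UMIs gave 3720 (trend toward the bottom), 1217 (trend toward the tip), 3102 (higher in V1 than V6), 1152 (higher in V6 than V1). Keeping only genes of at least 50 CPM, which tests fewer genes, gave 1307 (any difference), 845 (trend toward the bottom), 849 (trend toward the tip), 49 (V2 to V3), 11 (V5 to V6), 781 (higher in V1 than V6), 802 (higher in V6 than V1). No filter gave 3 (V3 to V4). Thinning, which leaves fewer counts, gave 171 (low middle), 10 (V2 to V3). Thinning with mouse as a block gave 868 (high middle), 646 (low middle), 943 (V1 to V2), 352 (V2 to V3), 167 (V3 to V4), 1 (V4 to V5), 105 (V5 to V6). DESeq2 gave 309 (V1 to V2), 102 (V2 to V3), 55 (V3 to V4), 41 (V5 to V6). A model of the 2 zones alone gave 0 (V1 to V2), 0 (V2 to V3), 2 (V3 to V4), 10 (V5 to V6). V2 to V6 gave 256 (trend toward the bottom), 862 (trend toward the tip). V3 to V6 gave 145 (any difference), 0 (high middle), 2 (low middle), 12 (lists), 2 (trend toward the bottom), 222 (trend toward the tip). V3 to V6 with mouse as a block gave 554 (any difference), 2 (high middle), 7 (low middle), 12 (lists), 75 (trend toward the bottom), 587 (trend toward the tip). V2 to V6 with mouse as a block gave 1191 (trend toward the bottom). The library pool as a block gave 4533 (any difference), 1267 (high middle), 969 (low middle), 1614 (V1 to V2), 409 (V2 to V3), 180 (V3 to V4), 134 (V5 to V6). Mouse and goblet score gave 556 (any difference), 61 (high middle), 6 (low middle), 31 (trend toward the bottom), 154 (trend toward the tip), 0 (V2 to V3), 184 (V3 to V4), 130 (V5 to V6), 28 (higher in V1 than V6), 152 (higher in V6 than V1). Camera with an estimated correlation gave 6 (lists).

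Leaving out a mouse in turn, which leaves fewer libraries, gave 1365 to 2043 (any difference), 138 to 381 (high middle), 123 to 196 (low middle), 1293 to 1777 (trend toward the bottom), 0 to 107 (V1 to V2), 0 to 18 (V2 to V3), 0 to 2 (V3 to V4), 13 to 26 (V5 to V6), 982 to 1464 (higher in V1 than V6). Leaving out a single library gave 1848 to 2128 (trend toward the tip), 1771 to 2230 (trend toward the bottom), 1569 to 1887 (higher in V6 than V1), 1264 to 1814 (higher in V1 than V6), 20 to 21 (lists).

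Over all lists and alternatives, 1099 values kept their direction and side of the threshold, 19 were no longer past it, 22 passed it newly and 13 reversed. For named genes these numbers were 3246, 387, 11 and 51. Median list slopes that reversed were, over V3 to V6, amino acid and peptide transporters -0.037, antigen presentation and interferon -0.011, brush-border peptidases and disaccharidases -0.00383, sugar transport and fructose metabolism -0.095, xenobiotic and glutathione metabolism -0.026. The values with mouse as a block were amino acid and peptide transporters -0.033, brush-border peptidases and disaccharidases 0.019, sugar transport and fructose metabolism -0.091, xenobiotic and glutathione metabolism -0.013 over V3 to V6, where the brush border is reversed by the sign of camera, and sugar transport and fructose metabolism -0.031 over V2 to V6. V2 to V6 without the block gave sugar transport and fructose metabolism -0.034, V1 to V5 gave enteroendocrine cells -0.32, and mouse with goblet score gave endoplasmic reticulum protein processing -0.00309.

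Gene slopes that reversed over V3 to V6 were Acaa1a -0.00786, Akr1b7 -0.057, Anpep -0.14, Atp2b1 -0.030, Bax 0.035, Ces2e -0.000921, Dpp4 -0.038, Ido1 0.061, P4hb -0.00173, Pigr -0.084, Slc15a1 -0.00538, Slc30a10 -0.00970, Slc5a1 -0.097, Slc5a11 -0.10, Slc5a9 -0.017, Smad4 -0.073, Zg16 0.017. With mouse as a block they were Acaa1a -0.00895, Akr1b7 -0.052, Anpep -0.12, Atp2b1 -0.034, Bax 0.037, Dpp4 -0.040, Ido1 0.11, Pigr -0.084, Slc30a10 -0.019, Slc5a1 -0.098, Slc5a11 -0.10, Slc5a9 -0.015, Smad4 -0.076, Zg16 0.043. None of these passed the test in the new direction. With mouse and goblet score the slopes were Ccl6 0.055, Clca1 0.083, Eif2s2 0.020, Ido1 0.12, Klk1 0.072, Manf 0.000336, Rep15 0.016, Spink4 0.098, Ssr2 0.014, Tff3 0.085, Zg16 0.052. For V6 minus V1 they were Ccl6 0.13, Clca1 0.46, Ido1 0.78, Klk1 0.35, Spink4 0.34, Tff3 0.43, Zg16 0.30, and for V2 to V3 Klk1 0.12, Tff3 0.074. The goblet score is made from Ccl6, Clca1, Rep15, Spink4, Tff3, Zg16 and the other genes of their list, so that reversal follows from its construction for these.

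The slope of genes detected, -82.5 per zone in all libraries (permutation p = 0.147), passed the threshold over V1 to V5 (-179.6, permutation p = 0.0159) and after thinning (-91.8, permutation p = 0.00261). The slope of the mitochondrial share, 0.823, was 0.317 over V2 to V6 (permutation p = 0.312) and -0.197 over V3 to V6 (permutation p = 0.646).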

Other observations

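The tests of chance given here were set before their results were seen, other than the comparison with splits that part every mouse, which was chosen after the results were seen.

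Other endocrine genes beside those of the report also differed between zones. Cck had 227 ± 153 CPM in V1, 59.5 ± 44.9 in V4 and 981 ± 106 in V6 (SD, n = 4), and its V6 minus V1 was 2.11 ± 0.62 (adjusted p = 0.0113). Ghrl had 38.7 ± 33.0 CPM in V1 and 174 ± 113 in V6 (SD, n = 4), with a V6 minus V1 of 2.16 ± 0.91 (adjusted p = 0.0666), higher in 4 of 4 mice, which passed with mouse as a block (2.28, adjusted p = 0.0279). Pyy changed by 2.09 ± 0.71 (adjusted p = 0.0261), and the glucagon gene Gcg by -0.70 ± 0.93 (adjusted p = 0.573; -0.71 with mouse as a block, adjusted p = 0.444). Gcg passed in neither model, although it was lower in V6 in 4 of 4 mice. Cck, Ghrl, Pyy and Gcg were chosen after their values were seen.

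Chance orders of the zones within mice were tried for the trend and its lists. For the trend, with 4189 genes, 1 of 100 orders, the true one, gave as many, and the next gave 494. For any difference, with 2556 genes, 1 of 100 did (highest other 1), and for curvature, with 693, 1 of 100 did (highest other 0). Chance is excluded at that level for these. For the 20 lists called by camera, 12 of 100 orders gave as many, the highest other being 21, so chance orders are not excluded for the number of lists.

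For 2 zones, the 35 splits of their 8 libraries were tried. The real split, 1 of 35, gave the most genes for V6 against V1 (3619, highest other 1), V1 to V2 (141, highest other 77), V2 to V3 (27, highest other 3), V3 to V4 (6, highest other 0) and V5 to V6 (25, highest other 2). For V4 to V5, where edgeR called 0 genes (171 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom), all 35 of 35 splits gave as many, with 3 in the highest other. Of the 35, 8 splits part all 4 mice as the real one does, and no other of these gave any gene in edgeR. The split with 77 does not part all 4 mice. Since the mouse numbers pair the libraries, these 8 are the like splits, and they are too few for a share under 0.05.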
